A study of Escherichia coli with 4 samples.

How the data were processed

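Gene expression of Escherichia coli MG1655 was measured in continuous culture, in steady state with air at 0.4 l/min and at 5, 10, 15 and 60 min after the air was switched off. Total RNA was labelled with Cy3 or Cy5 and hybridised to 10 slides of printed probes, 2 channels per slide. Each of the 5 groups (aerobic and the 4 times) holds 4 channels, of which as many were labelled with Cy3 as with Cy5. Per the labels, the channels come from 2 separate chemostat cultures per condition, each labelled both ways, but which slide holds which culture is not given in the sources used here. Channels were therefore the unit of the tests, and p-values measure the spread between channels, which is partly technical.

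The scanner tables hold spot intensity on a linear scale, one table per channel, quantified with ImaGene 5.1, per the file headers. The group, slide and dye of each channel were taken from the deposited names of these tables. Tables of the aerobic channels were deposited again with each time, and all 12 such copies were identical, so each channel was used once. The series value table holds signed fold changes of each time against aerobic as deposited by the authors, who used GeneSight 4 after a LOWESS normalization, per the labels. The labels call these values log2, but none of them lies between -1 and 1, as in a table of fold changes in which a decrease is written as a negative fold. Their medians were -1.00, -1.00, 1.01 and -1.01 at 5, 10, 15 and 60 min. Their direction is time over aerobic, since 19 of 20, 48 of 49, 74 of 74 and 61 of 61 called genes had the same sign in them as in the fit. Pearson's r across probes, which are not independent replicates, was 0.442, 0.588, 0.671 and 0.616. How these values were centred stays unknown, and they served only as an alternative.

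From the intensities, the mean signal of each spot was corrected with its median background by the normexp method with an offset of 50, and log ratios were normalized within each slide by loess and average intensities between slides by quantiles (limma 3.58.1 in R 4.3.3, with statmod 1.5.0). Each slide holds 4608 spots, of which 322 were controls, given no weight in the loess curves and left out of the tests. Spots with the quantification software's flag for poor quality were left out, which removed 25.1% of the values of the probes kept. A spot counted as well above background where its mean signal exceeded the mean background by 2 background SD, and a probe was kept where this held in at least 4 of the 20 channels. That kept 3682 of 4286 gene probes, with 3604 gene names. Names came from the platform annotation for 4087 probes, each with 1 symbol, and 0 probes had several. The other 199 probes were not listed there: 128 were named by matching the name in the scanner tables to RefSeq genes of assembly ASM584v2, and 71 kept the name in those tables. No coordinates are given because the sources used here name no genome build. For the 73 genes with several kept probes, the probe with the highest mean intensity was taken, and none of the genes named in the text is among them.

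All 20 channels entered a single limma fit with group and dye as terms and slide as a random block (intraspot correlation 0.533), so that all groups share the estimate of the spread. Each time was compared with aerobic, successive times were compared directly, and an F test covered all 4 times. P-values were adjusted by the Benjamini-Hochberg method over all probes with a value, and the threshold was 0.05. Fold changes are log2 values with the standard error of the fit after the ± sign, and n counts channels with a value. Where no channel of a group was well above background, the text gives a bound ("at least N-fold"). It sets the mean of the brighter group against the mean, per channel of the dimmer group, of the higher of the probe's own value and the lowest value well above background in that channel. The bound is left out where it is under 1.

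The tests, the alternatives, 24 gene lists and the rule for naming genes were fixed before the data were examined. The rule takes, for each time against aerobic, the 10 highest and 10 lowest changes past the threshold with the same sign in every fit that leaves out 1 slide. It takes the 5 highest and 5 lowest for each comparison of successive times, and up to 4 members of each list with the largest change past the threshold. It always names cydA, cydB, cyoA, sdhC, adhE, pflB, grcA, frdA, narG, katG, arcA and fnr. Genes named outside this rule were chosen after their values were seen, and the text says so.

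The lists hold 436 genes, of which 393 were measured. They are the TCA cycle and glyoxylate shunt, pyruvate dehydrogenase, cytochrome bo3 oxidase, cytochrome bd oxidases, NADH dehydrogenases, nitrate and nitrite respiration, fumarate and DMSO respiration with C4-dicarboxylate uptake, hydrogenases and formate hydrogenlyase, fermentation, glycolysis, fatty acid oxidation with acetate and lactate use, and ATP synthase. The others are the oxidative stress response, siderophore iron uptake, ferrous iron uptake and iron storage, iron-sulfur cluster assembly, the nitric oxide response, ribonucleotide reductases, acid resistance, the general stress response, heat shock, ribosomal proteins, flagella and chemotaxis, and oxygen-responsive regulators. Each list was tested with limma's camera on the moderated statistics of the fit with a preset correlation of 0.01, adjusted over the 24 lists and 4 times, and over the 24 lists and 3 successive comparisons apart from these. The plan had been to run camera on channel values with the slide block removed. Gaps left by poor spots ruled this out, so the correlation between members was estimated, and the fry test run, on the data with all spots kept (intraspot correlation 0.493). Fry tests whether a list's genes move on balance in a single direction and does not compare them with other genes. Adjusted p-values of lists are given with the preset correlation unless an estimated one is named.

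Depth on arrays is signal over background, and the number of channels limits the precision. Between 68.3% and 84.1% of gene probes were well above background in the Cy3 channels, against 35.5% to 60.5% in the Cy5 channels. Slides were quantified on 4 days holding 5, 1, 1 and 3 slides, and changes were also computed within each day that holds both groups and with the day as a term. Each comparison within a day rests on 1 aerobic channel and on 1 to 3 channels of the time. Alternatives were no background correction or plain subtraction, spot medians, median centring or print-tip loess within slides, no normalization between slides, other filters on dim probes and on poor spots, slide as a fixed effect or left out, no dye term, array weights, the day as a term, each slide left out in turn, stricter thresholds, other list tests, and the deposited values. Fits without the 10 min channel of slide 15, and on the slides of day 1 or day 4 alone, were added after the data were seen.

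The fit was tested on simulated data made from the real means and spread of 3682 probes, in which 50 probes each were changed by log2 1, 2, 3 and 4. At 5 min it recovered 56% of log2 changes of 1 and 93.8% of changes of 2. The shares were 22% and 87.5% at 10 min, 27.1% and 87.2% at 15 min, and 32% and 89.4% at 60 min. False calls numbered 10, 8, 8 and 6 at these times, and 0 where no probe was changed. The simulated noise followed the fitted model, without effects of culture or day and without single channels lying apart. These numbers therefore cannot show errors from such sources. More probes were changed than were called in the real data, which eases the adjusted threshold, so recovery there may be lower.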

Results

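The data describe how transcript levels of Escherichia coli changed as a culture went from full aeration to micro-aerobic conditions. Samples were taken in the aerobic steady state and at 5, 10, 15 and 60 min after the air was switched off, with 4 channels in each group. Relative to aerobic cells, 20 probes differed at 5 min (6 higher, 14 lower), 49 at 10 min (20 higher, 29 lower), 74 at 15 min (20 higher, 54 lower) and 61 at 60 min (21 higher, 40 lower), and 86 differed at any of the 4 times in the F test of limma. The median log2 change over all probes lay between 0.01 and 0.02 at each time. The normalization sets this value near 0, so a shift shared by all transcripts could not be seen. Median signal was 2.19 to 4.21 times the background in Cy5 channels and 3.79 to 5.04 times in Cy3 channels, so that weak genes were seen less well in Cy5. When slide was fitted as a fixed effect, which keeps only ratios within slides, 2, 0, 0 and 2 probes passed at the 4 times. No slide held aerobic RNA together with RNA of 10 or 15 min. Aerobic channels shared slides 23, 24 and 39 with 5 min and slide 26 with 60 min. Those of slides 23 and 24 were quantified on days 2 and 3, which hold no channel of 10, 15 or 60 min. The counts at 10 and 15 min thus rest largely on intensities compared between slides.

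**Figure D1:**
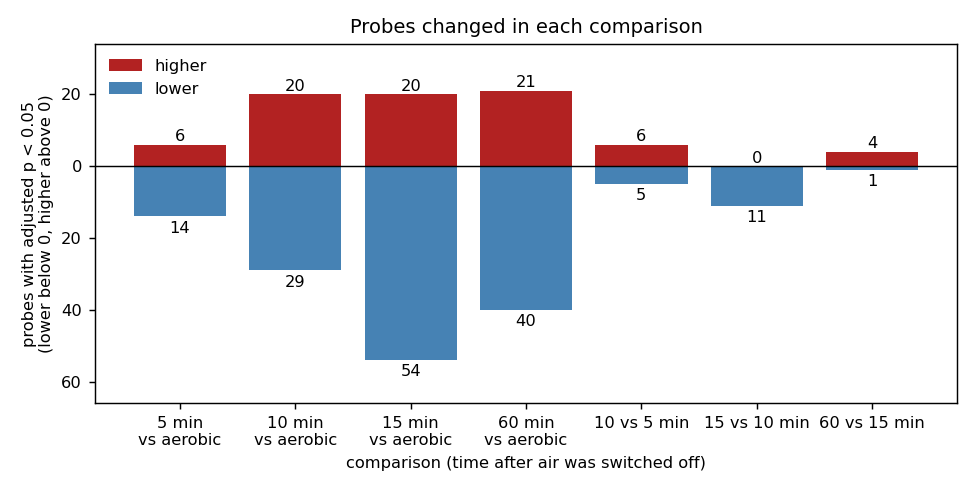
Numbers of probes with adjusted p under 0.05 in each comparison, drawn above 0 where the later time was higher and below 0 where it was lower. Against aerobic cells the count was 20 at 5 min and 74 at 15 min, and between successive times it was 11, 11 and 5.

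Which genes differed at 5 min was asked first. In the regrouping of channels described below, 2 of 35 groupings, the real one included, gave as many genes, so chance is not excluded for this count. The 6 genes that rose were feoA, ompW, copA, glpF, narG and ydfJ, and the 14 that fell included genes of purine, pyrimidine and methionine synthesis. The ferrous iron transport gene feoA rose by 2.13 ± 0.35 (n = 3 against 3 aerobic channels, adjusted p = 0.0265), the outer membrane protein gene ompW by 2.55 ± 0.35 (n = 3 against 3, adjusted p = 0.0116), the copper exporter gene copA by 1.49 ± 0.32 (n = 4 against 4, adjusted p = 0.0418) and the glycerol facilitator gene glpF by 1.70 ± 0.34 (n = 4 against 4, adjusted p = 0.0265). The gene narG, for the catalytic subunit of nitrate reductase A, was at least 1.03-fold higher (adjusted p = 0.0225), and ydfJ, not well above background in aerobic cells, also passed (adjusted p = 0.0265). The methylenetetrahydrofolate reductase gene metF was at least 2.18-fold lower (adjusted p = 5.78e-05), and metR, a regulator of methionine synthesis, changed by -1.66 ± 0.27. Of purine synthesis, purE changed by -2.52 ± 0.54 and purM by -1.89 ± 0.34, and purF was at least 1.78-fold lower. Of pyrimidine synthesis, carA changed by -2.01 ± 0.38 and pyrI by -1.47 ± 0.30. The ketol-acid reductoisomerase gene ilvC changed by -1.77 ± 0.32, ydcI by -1.76 ± 0.34 and ybaP by -1.41 ± 0.30. The spare-part gene of pyruvate formate-lyase, grcA, did not pass (at least 1.64-fold higher by the bound, adjusted p = 0.0841).

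Among the fixed lists, 4 shifted at 5 min. Nitrate and nitrite respiration was higher, with a median log2 change of 0.34 over 25 measured genes, 1 of which passed over all genes and 1 adjusted over the list alone (adjusted p of the list 5.16e-04). Ferrous iron uptake and storage was higher with a median of 0.60 over 6 genes, 1 of which passed and 3 adjusted over the list alone (adjusted p = 0.00833). Fermentation genes had a median of 0.29 over 14 genes, of which 0 passed and 2 adjusted over the list alone (adjusted p = 0.00831). Genes of fatty acid oxidation and acetate and lactate use had a median of -0.61 over 14 genes, of which 1 passed, the fatty acid transporter gene fadL (-1.28 ± 0.25), and 2 adjusted over the list alone. That list's adjusted p was 2.74e-04, and 0.0674 with an estimated correlation, while the other 3 kept adjusted p = 0.00456, 0.0125 and 0.0362. All values of called genes had the pooled sign within each quantification day, 14 of 14, 20 of 20 and 19 of 19, though the genes were chosen from the pooled data. In day 1 and on slides 23 and 24 the list medians were 0.16, 0.41 and 0.11 for nitrate respiration, 0.92, 1.79 and 0.57 for ferrous iron uptake, 0.31, 0.68 and -0.09 for fermentation and -0.73, -0.91 and -0.08 for fatty acid oxidation. The count fell from 20 to 1 without slide 23 or without slide 39, and to 2 with the quantification day as a term.

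At 10 min, the genes that were higher included narG and nirD and some genes of iron and copper transport and histidine synthesis, and those that were lower included 6 genes of fatty acid, acetate and lactate use and the single genes sdhC and iscR. The gene grcA was at least 5.27-fold higher (adjusted p = 0.0092), nirD, for the small subunit of nitrite reductase, at least 3.21-fold, and narG at least 2.62-fold. The cytochrome bd-I oxidase gene cydB rose by 1.37 ± 0.30 (n = 4 against 3, adjusted p = 0.0221) and the formate channel gene focA by 1.31 ± 0.30. Of the ferrous iron transporter, feoB rose by 2.50 ± 0.46 and feoC by 1.71 ± 0.35. Of copper export, copA rose by 2.69 ± 0.47 and cusF by 1.75 ± 0.31. The histidine synthesis genes hisD and hisI rose by 2.52 ± 0.39 and 1.95 ± 0.39, and bdcA was at least 2.95-fold higher. In hisD the 10 min channel of slide 15 lay at 10.96 in log2 intensity and the other 3 at 13.1 to 13.5.

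Of the genes that were lower at 10 min, 3 lie in the acetate uptake operon: acs, for acetyl-CoA synthetase, changed by -1.72 ± 0.36, yjcH by -3.23 ± 0.59 and the acetate transporter gene actP by -2.81 ± 0.58. The lactate transporter gene lldP changed by -2.17 ± 0.40 and fadL by -2.10 ± 0.33. The succinate dehydrogenase gene sdhC changed by -3.20 ± 0.67 (n = 3 against 2, adjusted p = 0.0467), and iscR, for the regulator of iron-sulfur cluster assembly, by -3.18 ± 0.51 (n = 2 against 3). The aspartate transcarbamoylase genes pyrB and pyrI changed by -2.27 ± 0.42 and -3.00 ± 0.40. The nucleoside diphosphate kinase gene ndk was at least 10.3-fold lower, arnC at least 2.65-fold and glcC at least 1.92-fold, and lhgD, for L-2-hydroxyglutarate dehydrogenase, changed by -2.85 ± 0.45 (n = 2 against 4).

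At 10 min, 10 lists shifted. Fatty acid oxidation and acetate and lactate use had a median of -1.66, with 6 of 14 genes lower and 10 adjusted over the list alone (adjusted p = 3.83e-13, and 1.08e-04 with an estimated correlation). Nitrate and nitrite respiration had a median of 0.60, with 2 of 26 higher and 7 adjusted over the list alone (adjusted p = 3.77e-08). Fermentation had a median of 0.39 with 2 of 13 higher, and 3 adjusted over the list alone (adjusted p = 0.0059). Ferrous iron uptake and storage had a median of 1.31 with 2 of 6 higher, and 3 adjusted over the list alone (adjusted p = 0.00831). Iron-sulfur cluster assembly had a median of -0.31 with 1 of 14 lower, and 2 adjusted over the list alone (adjusted p = 0.00908). With an estimated correlation these 4 kept adjusted p = 9.99e-06, 0.0251, 0.0125 and 0.0125. The calls of 5 lists were lost with an estimated correlation. They were the TCA cycle (median -0.58, 1 of 17 lower, 6 adjusted over the list alone, adjusted p = 1.53e-04, and adjusted p = 0.315 with an estimated correlation) and cytochrome bd oxidases (median 0.66, 1 of 7 higher, 2 adjusted over the list alone, adjusted p = 0.00767, and adjusted p = 0.139 with an estimated correlation). Fumarate and DMSO respiration (median 0.53, 0 of 18 passing, adjusted p = 0.0148, and adjusted p = 0.0872 with an estimated correlation), the general stress response (median -0.42, 0 of 17 passing, adjusted p = 0.0482, and adjusted p = 0.445 with an estimated correlation) and heat shock (median 0.43, 0 of 17 passing, adjusted p = 0.0352, and adjusted p = 0.554 with an estimated correlation) were the others.

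Within quantification days 1 and 4, all called genes with a value had the pooled sign at 10 min (40 of 40 and 28 of 28). The genes were chosen from pooled data that include these channels. Days 1 and 4 hold 3 channels and 1 channel at 10 min, against 1 aerobic channel each. The median of fatty acid oxidation was -1.52 and -1.83 in these days and that of nitrate respiration 0.52 and 0.22, whereas that of the TCA cycle was -1.13 and 0.61 and that of iron-sulfur cluster assembly -0.28 and 0.06. With the day as a term 14 probes passed in place of 49. Without slide 17, 23, 29 or 39 the count was 14, 24, 29 or 26, and without the 10 min channel of slide 15 it was 46. Without that channel the TCA cycle had a median of -0.37 with 0 of 17 passing (adjusted p = 0.00883), and NADH dehydrogenases (median 0.33, adjusted p = 0.0228) and glycolysis (median 0.27, adjusted p = 0.0466) passed. With the day as a term fumarate and DMSO respiration did not pass (adjusted p = 0.0611), and the median of cytochrome bd oxidases was 1.21 (adjusted p = 1.27e-04).

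At 15 min the count was 74, and 54 of these were lower. The genes of acetate use lay far below aerobic cells: acs changed by -3.51 ± 0.36 (n = 3 against 3, adjusted p = 9.19e-05) and yjcH by -4.45 ± 0.62, and actP was at least 10.9-fold lower. Of the TCA cycle, the citrate synthase gene gltA changed by -1.98 ± 0.33 (n = 4 against 4), the aconitase gene acnB by -2.34 ± 0.33 and the succinate dehydrogenase gene sdhB by -3.12 ± 0.63. Of iron-sulfur cluster assembly, iscR changed by -2.77 ± 0.54 (n = 2 against 3), the cysteine desulfurase gene iscS by -1.89 ± 0.40 and the scaffold gene iscU by -1.49 ± 0.34. Not every fit that left out a slide gave a value for iscR at 15 min, and its sign was kept where there was one. The gene fadL changed by -2.03 ± 0.34 and lldP was at least 2.35-fold lower. Of sulfate assimilation, the sulfite reductase gene cysJ was at least 7.08-fold and the sulfate uptake gene cysP at least 10.5-fold lower. The genes pyrB and pyrI were at least 9.22-fold and 7.91-fold lower, leuA of leucine synthesis changed by -2.76 ± 0.49 (n = 2 against 3), lhgD by -2.76 ± 0.41, and osmY, of the general stress response, by -1.24 ± 0.27.

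Higher at 15 min were ompW (3.33 ± 0.49), bssR, a regulator of biofilm formation (1.86 ± 0.30), feoB (2.31 ± 0.51), feoC (1.78 ± 0.36), copA (2.16 ± 0.43), the copper efflux gene cusB (1.81 ± 0.38) and cydB (1.39 ± 0.30). The bounds were at least 3.28-fold for grcA, 2.19-fold for nirD, 2.86-fold for the nitrate reductase chaperone gene narJ, 2.91-fold for bdcA and 3.63-fold for the cytochrome c maturation gene ccmC. The bound for narG, with 1 channel at 15 min, was 2.85-fold, and its sign had no value without that slide.

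Of the lists, 8 shifted at 15 min. The TCA cycle had a median of -1.64 with 4 of 18 genes lower and 12 adjusted over the list alone (adjusted p = 2.00e-11, and adjusted p = 0.0600 with an estimated correlation), and its within-day medians were -1.81 and -1.94. Fatty acid oxidation and acetate and lactate use had a median of -1.54 with 5 of 14 lower and 12 adjusted over the list alone (adjusted p = 7.17e-13, and 1.25e-04 with an estimated correlation). Nitrate and nitrite respiration had a median of 0.59 with 3 of 26 higher and 5 adjusted over the list alone (adjusted p = 3.78e-07, and 3.95e-05 with an estimated correlation). Iron-sulfur cluster assembly had a median of -0.36 with 3 of 13 lower and 3 adjusted over the list alone (adjusted p = 0.00264, and 0.00356 with an estimated correlation). The general stress response had a median of -0.53 with 1 of 17 lower and 8 adjusted over the list alone (adjusted p = 2.76e-04, and adjusted p = 0.0872 with an estimated correlation). Fermentation (median 0.35, 1 of 14 higher, 2 adjusted over the list alone, adjusted p = 0.0410), fumarate and DMSO respiration (median 0.40, 0 of 18 passing, adjusted p = 0.0432) and heat shock (median 0.32, 0 of 17 passing, 1 lower adjusted over the list alone, adjusted p = 0.0482) had adjusted p = 0.106, 0.168 and 0.615 with an estimated correlation. Within days 1 and 4 the median was -0.15 and 0.55 for fermentation, -0.07 and 0.98 for fumarate respiration and 0.85 and -0.35 for heat shock. Fermentation and heat shock did not pass without the 10 min channel of slide 15 (adjusted p = 0.0594 and 0.0584). Of the called genes with a value, 58 of 58 and 41 of 43 had the pooled sign in these days, though they were chosen from the pooled data. Days 1 and 4 hold 3 channels and 1 channel at 15 min, against 1 aerobic channel each. At 15 min with the day as a term fumarate respiration did not pass (adjusted p = 0.105), cytochrome bd oxidases passed (median 0.92 in place of 0.32, adjusted p = 0.00139 in place of 0.0525), as did pyruvate dehydrogenase (adjusted p = 0.0472), and 39 probes passed, and without slide 21, 22 or 39 the count was 34, 40 or 41.

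After 60 min, the change in ompW was 5.19 ± 0.59 (n = 2 against 3, adjusted p = 5.37e-04) and that in bssR 2.97 ± 0.28 (n = 4 against 4, adjusted p = 2.93e-06). The gene ydfZ rose by 2.34 ± 0.26. Of the copper and silver efflux operon, cusF rose by 2.30 ± 0.30, cusB by 2.03 ± 0.32 and cusC by 1.68 ± 0.28, and copA was also higher (adjusted p = 0.0123). The gene cydB rose by 1.58 ± 0.28, feoC by 1.59 ± 0.34, focA by 1.14 ± 0.27 and bidA by 1.65 ± 0.34. The gene grcA was at least 5.21-fold higher (adjusted p = 7.30e-04), srsR at least 1.38-fold, and the periplasmic nitrate reductase gene napA at least 2.20-fold. The value of napA was set against a single aerobic channel. Not every fit that left out a slide gave a value for it, and its sign was kept where there was one. The gene narG, not well above background in aerobic cells, did not pass (adjusted p = 0.0806).

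Lower at 60 min were acs (-3.56 ± 0.37, adjusted p = 3.84e-05), yjcH (-3.77 ± 0.67) and actP (-3.07 ± 0.59), and fadL and lldP were at least 3.04-fold and 2.91-fold lower. Of the TCA cycle gltA changed by -1.71 ± 0.31 and acnB by -1.64 ± 0.30, and of iron-sulfur cluster assembly iscU changed by -1.93 ± 0.32 and iscS by -1.69 ± 0.31. The gene pyrB changed by -2.92 ± 0.42 and pyrI was at least 4.88-fold lower. The general stress genes osmY and yiaG changed by -1.10 ± 0.25 and -0.97 ± 0.22. Bounds for ydcI, arnC and yncG were at least 3.24-fold, 3.32-fold and 2.67-fold lower.

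At 60 min, 8 lists shifted. Fatty acid oxidation and acetate and lactate use had a median of -1.65 with 5 of 14 genes lower and 10 adjusted over the list alone (adjusted p = 1.59e-13, and 8.15e-05 with an estimated correlation). Iron-sulfur cluster assembly had a median of -0.39 with 2 of 12 lower and 3 adjusted over the list alone (adjusted p = 6.71e-04, and 9.41e-04 with an estimated correlation). Nitrate and nitrite respiration had a median of 0.29 with 1 of 26 higher and 3 adjusted over the list alone (adjusted p = 0.00831, and 0.0362 with an estimated correlation). The TCA cycle (median -0.94, 2 of 18 lower, 7 adjusted over the list alone, adjusted p = 3.78e-07) and the general stress response (median -0.73, 2 of 16 lower, 6 adjusted over the list alone, adjusted p = 1.62e-04) had adjusted p = 0.169 and 0.0674 with an estimated correlation. Cytochrome bd oxidases (median 0.47, 1 of 7 higher, 2 adjusted over the list alone, adjusted p = 0.0148), fermentation (median 0.15, 2 of 14 higher, 2 adjusted over the list alone, adjusted p = 0.0148) and ferrous iron uptake (median 0.85, 1 of 6 higher, 3 adjusted over the list alone, adjusted p = 0.0359) had adjusted p = 0.192, 0.0594 and 0.0516 with an estimated correlation. Within days 1 and 4 the medians were -1.25 and -1.40 for fatty acid oxidation, -0.35 and -0.54 for iron-sulfur cluster assembly, -0.01 and 0.16 for nitrate respiration, -0.10 and 0.54 for fermentation and 1.34 and -0.16 for ferrous iron uptake. Of the called genes with a value, 44 of 45 and 39 of 39 had the pooled sign in these days, though they were chosen from the pooled data. Days 1 and 4 hold 1 channel and 3 channels at 60 min, against 1 aerobic channel each. With the day as a term nitrate respiration (adjusted p = 0.0630) and ferrous iron uptake (adjusted p = 0.0929) did not pass, the median of cytochrome bd oxidases was 0.93 (adjusted p = 2.40e-04), and 28 probes passed, and the count was 30 without slide 26 and 36 without slide 29.

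**Figure D2:**
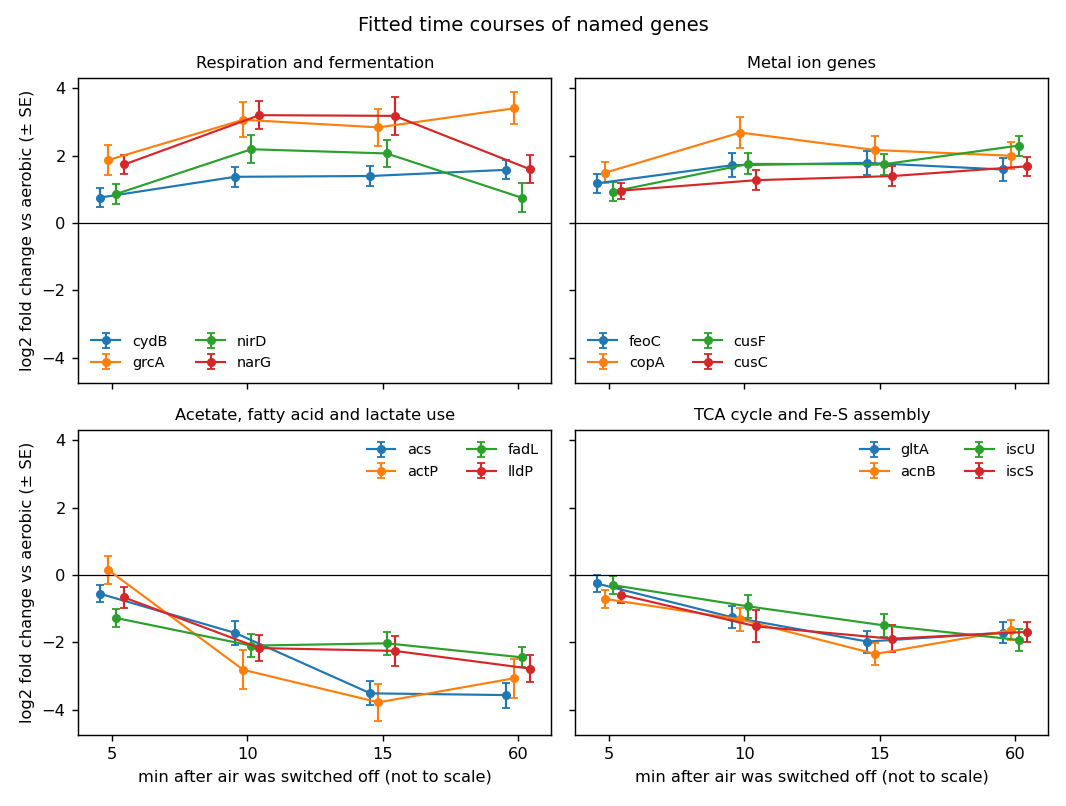
Fitted log2 fold changes against aerobic cells (points, with standard errors as bars) at 5, 10, 15 and 60 min for 16 genes in 4 panels. Fitted values are drawn also where a group had no channel well above background, as for grcA and narG, for which the text gives bounds. The change in acs was -1.72 at 10 min and -3.51 at 15 min.

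Some genes named in advance did not pass at any time. The other cytochrome bd-I gene cydA changed by 1.60 ± 0.50 at 60 min (adjusted p = 0.140), the cytochrome bo3 oxidase gene cyoA by -1.25 ± 0.67 at 10 min (adjusted p = 0.509) and the alcohol dehydrogenase gene adhE by 1.01 ± 0.33 at 10 min (adjusted p = 0.217). At 60 min the fumarate reductase gene frdA changed by 0.89 ± 0.62 (adjusted p = 0.616) and the catalase gene katG by 0.11 ± 0.27 (adjusted p = 0.921). The pyruvate formate-lyase gene pflB, not well above background in aerobic cells, was at least 1.64-fold higher by the bound at 60 min but did not pass (adjusted p = 0.216). The oxygen-responsive regulator genes arcA and fnr changed by -0.63 ± 0.28 (adjusted p = 0.333) and -1.02 ± 0.50 (adjusted p = 0.414) at 60 min. The gene sdhC passed at 10 min and not at 15 min (-2.57 ± 0.88, adjusted p = 0.222).

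The remaining lists did not pass at any time against aerobic, and their medians at 60 min were as follows. Pyruvate dehydrogenase had -1.37 over 2 genes (adjusted p = 0.0525), cytochrome bo3 oxidase -0.66 over 5 (adjusted p = 0.247), NADH dehydrogenases 0.11 over 14 (adjusted p = 0.116) and hydrogenases and formate hydrogenlyase 0.39 over 21 (adjusted p = 0.0893). Glycolysis had -0.10 over 17 genes (adjusted p = 0.794), ATP synthase -0.29 over 8 (adjusted p = 0.312), siderophore iron uptake 0.16 over 25 (adjusted p = 0.557) and acid resistance -0.65 over 10 (adjusted p = 0.0971). The median was 0.06 for 53 ribosomal protein genes (adjusted p = 0.717) and -0.10 for 12 oxygen-responsive regulators (adjusted p = 0.531). Signs of median, mean and test differed for the oxidative stress response (median 0.07, mean -0.03 over 15 genes, adjusted p = 0.909), the nitric oxide response (median -0.04, mean 0.01 over 9, adjusted p = 0.909), ribonucleotide reductases (median 0.00, mean -0.14 over 7, adjusted p = 0.699) and flagella and chemotaxis (median 0.06, mean -0.03 over 40, adjusted p = 0.942). At 60 min pyruvate dehydrogenase, NADH dehydrogenases and acid resistance passed with the day as a term (adjusted p = 0.0307, 0.0141 and 0.0141), and without the 10 min channel of slide 15 pyruvate dehydrogenase passed at 15 and 60 min (adjusted p = 0.0448 and 0.0430). Of the flagella and chemotaxis list, 1 gene passed, at 15 min. It was tcyJ (-1.31 ± 0.30), whose product binds cystine.

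**Figure D3:**
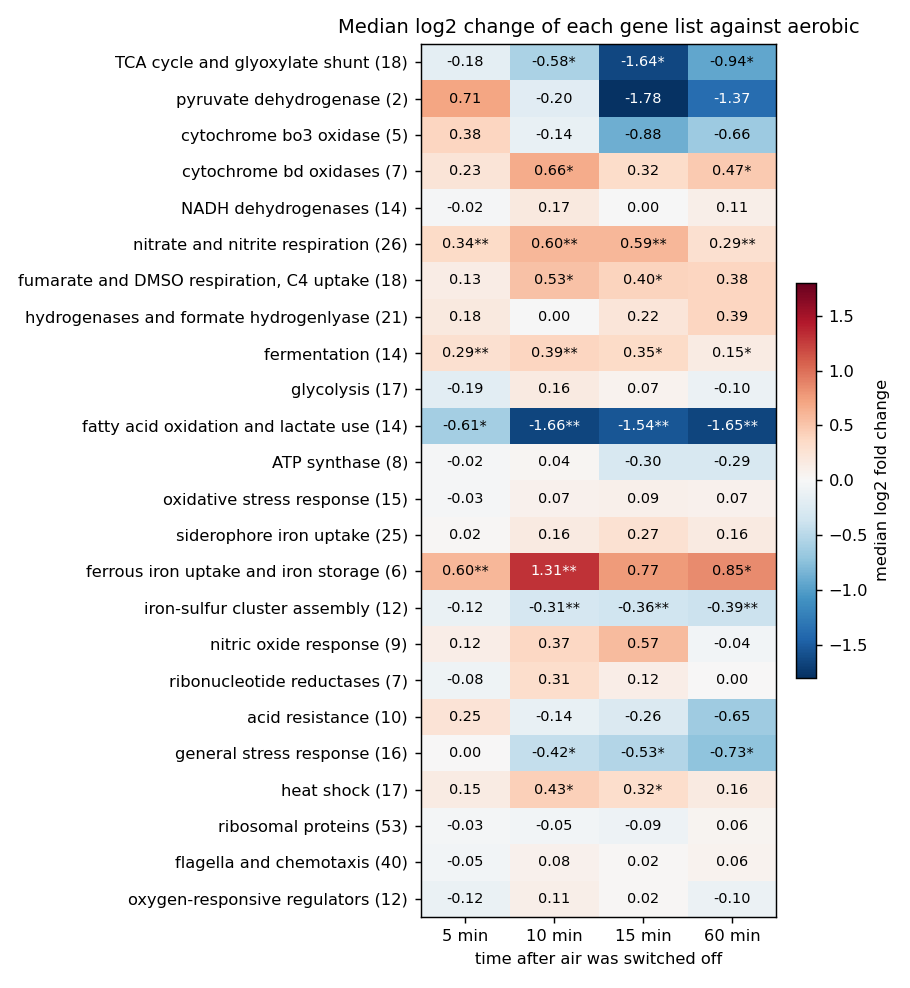
Median log2 fold change of each fixed gene list (rows, with the number of genes measured at 60 min) at each time (columns), with colour from lower (blue) to higher (red). A star marks a list with adjusted p under 0.05 at the preset correlation and 2 stars a list that also passes with an estimated correlation. Fatty acid oxidation and lactate use was -1.66 at 10 min and -1.65 at 60 min.

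Direct comparison of successive times asked when the changes took place. Between 5 and 10 min 11 probes differed, 6 higher and 5 lower. The genes hisD (1.81 ± 0.37), hisF (1.48 ± 0.26), the ferritin-like gene ftnB (1.63 ± 0.28), ymgD (1.55 ± 0.30) and the C4-dicarboxylate transporter gene dcuC (1.50 ± 0.28) rose, each with adjusted p = 0.0357 or 0.0294. The genes actP (-2.97 ± 0.59), yjcH (-2.56 ± 0.52), pyrB (-2.53 ± 0.40), lhgD (-2.36 ± 0.42) and ydcA (-1.31 ± 0.26) fell. With median centring within slides 3 were higher and 5 lower. With print-tip loess, limma called 0 probes there, and the count was 0 also without slide 21, 23 or 24. At an unadjusted p under 0.05 there were 357. Without slides 17, 22, 29 and 39 the counts were 2, 3, 3 and 7. Fatty acid oxidation fell in this interval (median -0.82 over 14 genes, adjusted p = 2.91e-07, and 0.0188 with an estimated correlation), as did iron-sulfur cluster assembly (median -0.32 over 13, adjusted p = 0.0181, and 0.0356 with an estimated correlation). Nitrate respiration (median 0.41 over 25, adjusted p = 0.00869) and the TCA cycle (median -0.49 over 17, adjusted p = 2.06e-04) had adjusted p = 0.0540 and adjusted p = 0.566 with an estimated correlation. With the day as a term nitrate respiration and iron-sulfur cluster assembly did not pass here (adjusted p = 0.0816 and 0.0856), nor did iron-sulfur cluster assembly without the 10 min channel of slide 15 (adjusted p = 0.0503).

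Between 10 and 15 min 11 probes were lower and 0 higher. Of these, cysU changed by -1.98 ± 0.32 (n = 2 against 2), the periplasmic folding catalyst gene fkpA by -1.95 ± 0.30, acs by -1.79 ± 0.31 and hisD by -1.74 ± 0.34, and cysJ was at least 2.80-fold lower. Without the 10 min channel of slide 15 the count was 13, hisD changed by -2.45 and fkpA did not pass (adjusted p = 0.143). Without slides 17, 21, 22, 25 and 29 the counts were 6, 1, 2, 7 and 4. The TCA cycle (median -0.72 over 17, adjusted p = 6.91e-04) and the general stress response (median -0.54 over 17, adjusted p = 0.00158) had adjusted p = 0.612 and adjusted p = 0.312 with an estimated correlation. Between 15 and 60 min 5 probes differed. The gene cysJ was at least 4.87-fold higher at 60 min (adjusted p = 0.00496), and the ribosomal protein gene rpsQ (1.85 ± 0.33), the nitrogen regulator gene glnB (1.74 ± 0.29) and the thiosulfate uptake gene tsuA (1.34 ± 0.23) rose, while ymgD fell (-1.94 ± 0.32). Nitrate respiration was lower at 60 than at 15 min (median -0.21 over 26, adjusted p = 0.00106, and 0.0188 with an estimated correlation). The nitric oxide response (median -0.25 over 9, adjusted p = 0.0354) and the TCA cycle (median 0.49 over 18, adjusted p = 0.00226) had adjusted p = 0.178 and adjusted p = 0.633 with an estimated correlation. The count of 5 became 0 without slide 22 or 26 and 11 without slide 15, and it was 3, 1, 1, 2, 2 and 3 without slides 17, 21, 23, 24, 25 and 29.

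**Figure D4:**
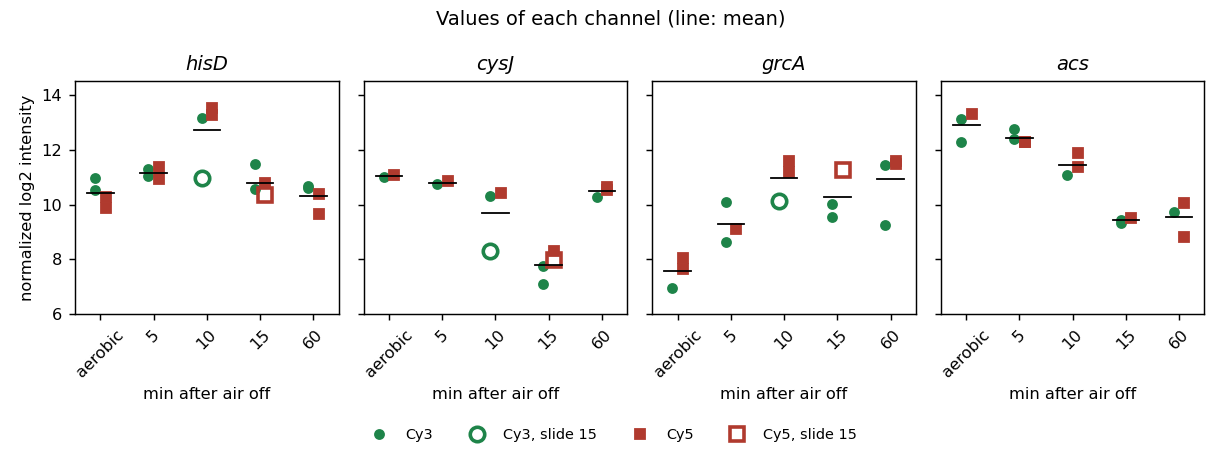
Normalized log2 intensity of each channel (Cy3 circles, Cy5 squares, slide 15 open) in the aerobic group and at each time for hisD, cysJ, grcA and acs, with the mean of each group as a line. The 10 min channel of slide 15 lies at 10.96 in hisD, below the other 3 channels at 13.1 to 13.5.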

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

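The quantification-day tests of copper and pyrimidine genes, the ribosomal protein test and all 3 tests on slide 15 were chosen after the results they bear on were seen. The predictions for other groupings of the channels and for print position were written before their values were seen, but the 3 patterns were picked from the data after many genes had been looked at.

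A single channel lay apart from the other 3 of its group in 5 named genes and 1 measure of signal. In grcA at 60 min the Cy3 channel of slide 26 was at 9.27 in log2 intensity against 11.4 to 11.6. In ydfJ at 10 min that of slide 21 was at 8.12 against 3 others at most 7.26. In cydB at 60 min that of slide 29 was at 14.03 against 13.3 to 13.4, and in fnr at 10 min the Cy5 channel of slide 29 was at 8.54 against 9.75 to 9.97. In hisD at 10 min the Cy3 channel of slide 15 was at 10.96 against 13.1 to 13.5. Signal over background of the Cy5 channel of slide 24, at 5 min, was 2.19 against 4.21 to 4.44. With 145 groups tested, chance gives about 7.25 such channels at a rate of 0.05, and 6 were found.

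Successive times differed by a direct test in 11 genes between 5 and 10 min, 11 between 10 and 15 min and 5 between 15 and 60 min. Of the lists, the median change between 5 and 10 min was -0.49 in the TCA cycle, 0.41 in nitrate respiration, -0.82 in fatty acid oxidation and -0.32 in iron-sulfur cluster assembly. Between 10 and 15 min it was -0.72 in the TCA cycle and -0.54 in the general stress response. Between 15 and 60 min it was 0.49 in the TCA cycle, -0.21 in nitrate respiration and -0.25 in the nitric oxide response. With an estimated correlation the calls of the TCA cycle (adjusted p = 0.566, 0.612 and 0.633), nitrate respiration between 5 and 10 min (0.0540), the general stress response (0.312) and the nitric oxide response (0.178) were lost.

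Control spots outside the gene probes also gave signal. A median over channels of 9.78% of the 46 control spots named ara and 6.02% of the 274 internal control spots were well above background.

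Whether any other arrangement of the channels gives counts as large was tested by regrouping the 8 channels of each comparison in all 35 ways. At 10, 15 and 60 min only 1 of 35, the real grouping, gave as many genes (49, 74 and 61, against at most 2, 4 and 4). Over all times it was 1 of 100 groupings, again the real one (86 against at most 4). This argues against a chance arrangement of single channels there but cannot exclude it, since 1 of 35 or of 100 is the lowest share possible. The same held between 5 and 10 min (1 of 35, 11 against at most 2) and between 10 and 15 min (1 of 35, 11 against at most 5). Those 2 counts moved with the processing, however. The first was 0 with print-tip loess and the second 1 without slide 21. At 5 min 2 of 35 gave as many genes, the real count being 20 and the highest other 25, and between 15 and 60 min 4 of 35 did (5 against 11), so chance is not excluded for those counts. The regrouping takes the channels as exchangeable, and since the channels of a culture cannot be kept together without knowing which they are, chance differences between the 2 cultures of each condition are not excluded at any time. The grouping with 25 genes sets both channels of slides 23 and 24, the only slides of their days, against the rest. With the day as a term 2 genes passed at 5 min. Of the lists, 1 of 35 groupings gave as many shifts at 10, 15 and 60 min (10, 11 and 10 against at most 9, 9 and 8, counted within each comparison), and 5 of 35 did at 5 min (4 against 6). Chance is therefore not excluded at 5 min. At the later times other groupings shifted nearly as many of the 24 lists at the preset correlation, so these counts barely set the real grouping apart. List calls at that correlation carry this limit.

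The first pattern is the rise of copper and silver efflux genes. If print position had caused it, probes printed beside the members or from the same dip should have moved along, but the median log2 change of 120 such probes at 60 min was -0.0104, against 1.68 in the 9 members. If quantification day had caused it, a median within a day should have been under 50% of the pooled one, but with all spots kept it was 1.73 in day 1 and 1.59 in day 4 (first run with poor spots left out, 1.62 and 1.79). The neighbouring probes argue against print position. The medians within days go against the day as the cause, but only weakly. They rest on 1 aerobic channel each, against 1 channel at 60 min in day 1 and 3 in day 4. The group was also picked from pooled data that include these channels. A response to the fall in oxygen may account for the rise of these genes and was not tested apart from the time itself.

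The second pattern is the fall of pyrimidine synthesis genes. Print position is argued against by a median of -0.0099 over 130 neighbouring probes, against -1.42 in the 9 members. A general fall of growth-related transcripts that takes in ribosomal protein genes is argued against by their median of 0.0561 ± 0.0404 (SE over 53 genes). A fall shared with other synthesis genes is not excluded. At 60 min the median was -1.43 in methionine synthesis and uptake and -0.58 in sulfate assimilation and cysteine synthesis, against -0.25 in purine and 0.09 in histidine synthesis. Quantification day remains a possible explanation: with all spots kept the median was -0.134 ± 0.575 in day 1 and -1.01 ± 0.454 in day 4 (SE over members), against -0.99 when pooled, so day 1 falls short of the 50% set for it, although its spread is wide. That test was first run with poor spots left out, where the medians at 60 min were -0.57 and -0.07 and the reading was the same. With poor spots left out, the medians of day 1 and day 4 were -0.76 and -0.95 at 10 min (pooled -1.24), which goes against the day, and -0.45 and 0.31 at 15 min (pooled -1.41), which does not, and with the day as a term the medians were -0.59, -0.96, -0.78 and -1.03 at 5, 10, 15 and 60 min, so the day is left open.

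The third pattern is the 10 min channel of slide 15. On a scale from 0, the mean of the 15 min channels, to 1, that of the 10 min channels, its median position was 0.217 over 7 genes that differed between these times without that slide, and 5 of the 7 lay nearer to 15 min. Being under 0.5, this is consistent with a channel that holds RNA like that at 15 min. Whether both channels of the slide hold the same RNA cannot be told apart: the SD of its log ratios was 0.631, against 0.618 in the lowest other slide, a gap of 0.0123 ± 0.0120, while by the median absolute deviation slide 15 was the lowest of the 10 (0.537, next 0.574) (by the prediction as first written, the rank alone argued against shared RNA, and the error of the gap was weighed only after the value was seen). A difference between the 2 cultures at 10 min as the cause is argued against, but only weakly: each culture was labelled with both dyes, so 1 Cy5 channel should lie with slide 15. For the test, 35 probes were chosen whose Cy3 values on slides 15 and 21 differed by a log2 of 2 or more. Of these, 29 had a value on slide 17 and 23 on slide 29. On a scale from slide 15 (0) to slide 21 (1), these Cy5 channels lay at 0.766 ± 0.0569 and 0.747 ± 0.0746 (SE over probes). Each value rests on a single Cy5 channel, and an SE over probes does not measure the spread between channels or cultures. An earlier form of the test, with 0.921 and 1.01 for them, chose its genes with slide 15 included and could not decide.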

How the results depend on the processing

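The fits without the 10 min channel of slide 15 and on day 1 or day 4 alone were chosen after the data were seen. Counts are given as total (higher/lower), in the order 5, 10, 15 and 60 min against aerobic (20, 49, 74, 61), 10 against 5 min, 15 against 10 min, 60 against 15 min (11, 11, 5) and any time (86), and where a setting is named with fewer counts the others stayed within 1.5 times. Spot medians gave 7 (1/6), 22 (7/15), 47 (12/35), 39 (11/28), then 4 (1/3) for 10 against 5, 3 (2/1) for 60 against 15 and 48 at any time. With all spots kept the counts were 43 (15/28), 107 (45/62), 130 (35/95), 110 (33/77), 6 (2/4), 17 (1/16), 8 (6/2) and 141. Slide as a fixed effect, which has fewer degrees of freedom and uses only ratios within slides, gave 2, 0, 0, 2, 0, 0, 0 and 2. No slide term gave 1 at 5 min, 26 (9/17) at 10 min, 34 (9/25) at 60 min, 2, 0 and 0 between times and 52 at any time. No dye term gave 1 at 5 min, 21 (6/15) at 10 min, 39 (12/27) at 60 min, 0, 3 and 1 between times and 46 at any time. Quantification day as a term gave 2, 14 (8/6), 39 (13/26), 28 (12/16), 0, 4, 1 and 43. Adjusted p under 0.01 left 1, 12 (6/6), 31 (7/24), 27 (8/19), 0, 4, 1 and 40. Array weights gave 6 (2/4) at 5 min, 18 (3/15) for 15 against 10 and 15 (11/4) for 60 against 15. No normalization between slides gave 34 (13/21) at 5 min, 5 (3/2) for 10 against 5 and 7 (0/7) for 15 against 10. Print-tip loess gave 0 for 10 against 5 and 17 (1/16) for 15 against 10, and plain background subtraction 6 (4/2) for 10 against 5 and 3 (3/0) for 60 against 15. For 60 against 15 min no background correction gave 11 (9/2), the filter on 50% of channels 8 (7/1) and leaving out every spot with a quality mark 12 (10/2). Without the 10 min channel of slide 15 the counts were 5 (4/1) for 10 against 5 and 9 (7/2) for 60 against 15. With limma, day 1 alone gave 0 in all 8 comparisons and day 4 alone 0 in the 5 it allows (10, 15 and 60 min, 15 against 10, 60 against 15), from fewer channels. At an unadjusted p under 0.05 all channels gave 392, 396, 482, 469, 357, 265, 263 and 497. With each slide left out in turn the counts ranged from 1 to 27, 14 to 62, 34 to 80, 30 to 66, 0 to 12, 1 to 12, 0 to 11 and 47 to 98, and list shifts from 22 to 35. Of the 96 list tests 30 shifted (17/13), and 14 (8/6) with an estimated correlation. Of 39 list calls in all comparisons, 32 stayed with the day as a term and 36 without the 10 min channel of slide 15, and 8 and 12 further list tests passed there. Of 124 called values of named genes, none reversed in any fit to the intensities. For genes named as highest or lowest, the naming rule had already required this of the fits that leave out 1 slide. Of the 124, 116 stayed called with no background correction, 67 with spot medians, 66 with no slide term and 55 with the day as a term. Between 72 and 114 stayed called without a slide, and only 4 of the 111 with a value when slide was a fixed effect. Of 103 called values that also have a deposited value, 73 lay within 1 residual SD of the deposited log2 change. Among the others ybaP at 5 min was reversed (0.505 against -1.41), and the rest kept their sign but differed by more than that in size. Where construction does not show it, the cause was not tested. Cy5 channels, with 2.19 to 4.21 times the background, limit what can be seen of weak genes.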

Other observations

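The 6 gene groups below and their tests were chosen after the genes with the largest changes had been seen, so their p-values are not independent evidence. Adjusted p-values here use an estimated correlation and cover these 6 groups, at the 4 times and in the 3 successive comparisons apart. Genes of copper and silver efflux had a median log2 change of 0.93, 1.36, 1.44 and 1.68 at 5, 10, 15 and 60 min over 9 genes, of which 1, 4, 5 and 5 passed (adjusted p = 0.00347, 9.74e-05, 9.74e-05 and 2.02e-05). At 60 min cusA rose by 1.61 ± 0.38 beside cusC, cusF and cusB, while the regulator gene cueR did not pass (0.18 ± 0.34, adjusted p = 0.884). Methionine synthesis and uptake had medians of -1.02, -1.29, -1.42 and -1.43 over 13 genes, of which 3, 2, 3 and 3 passed (adjusted p = 3.94e-04, 8.59e-04, 0.00111 and 3.54e-04), and the methionine uptake gene metQ changed by -2.65 ± 0.36 at 15 min and -2.31 ± 0.35 at 60 min. Pyrimidine synthesis had medians of -0.58, -1.24, -1.41 and -1.42 over 9 genes (adjusted p = 0.00121, 2.37e-04, 3.19e-04 and 3.29e-04). In pyrimidine synthesis 2, 2, 2 and 3 genes passed. The changes at 5 min were smallest on slide 24. In day 1 and on slides 23 and 24 the medians at 5 min were 0.87, 1.05 and 0.16 for copper and silver efflux. They were -1.29, -0.87 and -0.63 for methionine synthesis and uptake and -1.02, -1.06 and -0.16 for pyrimidine synthesis.

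Other groups moved at some times only. Purine synthesis was lower at 5 and 10 min, with medians of -0.78 and -0.71 over 13 genes (adjusted p = 8.59e-04 and 0.0133), and rose between 10 and 15 min (median 0.38, adjusted p = 0.0258). At 5 min its median was 0.09 in day 1, -0.90 on slide 23 and -0.16 on slide 24, so the fall at 5 min was not seen in every day. At 15 min its median was -0.09 (adjusted p = 0.598). Histidine synthesis was higher at 10 min, with a median of 1.37 over 9 genes, 4 of which passed (adjusted p = 8.82e-04), among them hisA (1.37 ± 0.33) and hisF (1.69 ± 0.30), having risen between 5 and 10 min (median 0.87, adjusted p = 0.00609). It fell between 10 and 15 min (median -0.76, adjusted p = 0.0418), was still higher than in aerobic cells at 15 min (median 0.78, adjusted p = 0.0373) and fell further between 15 and 60 min (median -0.54, adjusted p = 0.0258). Sulfate assimilation and cysteine synthesis was lower at 15 min, with a median of -1.59 over 14 genes, 8 of which passed (adjusted p = 4.16e-04), among them cysU (-2.16 ± 0.36), cysW (-2.08 ± 0.37), cysA (-1.32 ± 0.25) and cysD (-1.48 ± 0.30). That group fell between 10 and 15 min (median -1.36, adjusted p = 4.61e-05) and rose between 15 and 60 min (median 0.96, adjusted p = 7.92e-04). Without the 10 min channel of slide 15, 13 genes differed between 10 and 15 min, among them hisC (-3.88) and hisD (-2.45), which were lower, and purM (2.16), which was higher.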
